A study of Mus musculus with 3 samples.

How the data were processed

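The study measured RNA and surface proteins together (CITE-seq) in lineage-negative, KIT-positive cells sorted from mouse liver on postnatal day 0. There were 3 libraries, 1 each from Control mice, mice expressing the fusion MLL-ENL, and MLL-ENL mice with Skida1 deleted. Per the labels' protocols, the libraries were made from polyA RNA with the 10x Genomics single-cell 3' chemistry and feature barcodes. The deposited files hold raw UMI counts for 32285 genes and 10 antibody tags per cell barcode, with no normalization. Per the file headers the matrices came from Cell Ranger 6.1.2, whereas the submitters' processing notes name version 6.0.1 and build mm10. The lowest gene total of any listed barcode was 500 UMIs in Control, 501 in MLL-ENL and 500 in the Skida1-deleted library. Doublet removal, other filters and cell annotation are not given in the sources used here. Chromosome positions came from an annotation of GRCm38.p6, the assembly that mm10 names, joined by gene symbol.

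The matrices listed 6091 barcodes and 180656900 gene UMIs in Control, 11910 barcodes and 198773992 gene UMIs in MLL-ENL, and 10543 barcodes and 207395090 gene UMIs in the Skida1-deleted library. Cells were kept with at least 1000 UMIs, at least 500 genes and under 10% mitochondrial UMIs, which left 5777, 11148 and 9962 cells. Scrublet in scanpy 1.11.5 then called 391 doublets in Control (6.77%) and 558 in the Skida1-deleted library (5.60%), and these were removed. It called 0 in the MLL-ENL library, where the 994 cells with the highest scores were removed instead, at the expected rate of 0.8% per 1000 cells. The kept cells numbered 5386, 10154 and 9404, with median depths of 28013, 14704.5 and 17299 UMIs.

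The 3 libraries were clustered together without integration, with the Leiden method at resolution 1.0 on 30 principal components of 2000 variable genes and 15 neighbours. Mitochondrial, Rpl, Rps and sex-linked genes were left out of the variable genes. Clusters were named from 15 fixed marker lists, as "like" a class. The first naming rule, a standardized marker score, gave names at odds with the clusters' leading genes and was replaced after its output was seen. Under the rule used, a cluster took the class with the most markers among its top 50 genes. At least 3 markers had to lie at least 1.5-fold above the mean of clusters of other classes. A cluster stayed unnamed where another class had more markers among its top 10 genes. So it did where its depth was low and those genes held no marker of its class. It also stayed unnamed where its depth was low and its top 50 genes held at least 4 markers of another class. That last threshold, set after the clusters were seen, alone kept 1 cluster of 2613 cells out of the erythroid-like class. It held 0.186% of the kept cells in Control, 24.7% in MLL-ENL and 0.989% in the Skida1-deleted library.

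For each class UMIs were summed per library and scaled to all gene UMIs of the class as CPM. Differences were log2 ratios of (CPM + 1), and folds were ratios of CPM. Classes with at least 100 cells in every library were compared. Since each group had 1 library, no test between groups was possible, and no p-value was computed. Brackets give 95% intervals, exact Poisson for CPM, exact conditional binomial for folds of CPM and of cell shares, exact binomial (Clopper-Pearson) for shares of cells, and the log normal form for 1 odds ratio. They cover counting error only, not the differences between animals or preparations. No difference below has a replicate check. Counts of 3 or fewer are mostly given with their interval, though not for Ebf1 in erythroid-like cells or for 0 UMIs of Ddx3y. No fold was formed against 0 counts.

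Genes were named by a fixed rule. For each contrast in HSPC-like cells (hematopoietic stem and progenitor) these were the 12 highest and 12 lowest log2 ratios. Genes needed a CPM of at least 30 in either library and at least 50 UMIs over both. Mitochondrial, ribosomal protein, sex-linked, immunoglobulin and T cell receptor segment genes and unnamed gene models were left out. In other classes and in all kept cells the 5 highest and 5 lowest were taken. Skida1, Kmt2a, Mllt1 and up to 4 members of each gene list with the largest absolute log2 ratio were added, of which some are not reported here.

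The 30 gene lists were MLL-fusion targets, HoxA cluster, HoxB cluster, HSC program, B-lineage priming, lymphoid priming, granulocyte-monocyte program, megakaryocyte program, erythroid program, mast-basophil-eosinophil program, fetal-neonatal program, adult-like HSPC program, interferon response, MHC class I, MHC class II, S phase, G2M phase, cell cycle inhibitors, p53 targets, Polycomb repressive complexes, MLL and elongation complex, MYC and ribosome biogenesis, oxidative phosphorylation, glycolysis, cholesterol synthesis, heat shock, immediate early, sex-linked, homing and adhesion, and cytokine receptors and signalling. A member counted as measured at a CPM of at least 5 in either library of a contrast. Each list was described by its median log2 ratio, by its members at least 1.5-fold higher or lower, and by the percentile of its median among 10000 random lists matched on size and mean CPM (20 bins). The percentile describes these libraries and is not a test. Several lists share genes, and the HSC, B-lineage, lymphoid, granulocyte, megakaryocyte, erythroid and mast lists also share genes with the markers that named the clusters.

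Antibody counts were centred log ratios over the 10 tags within each cell. For shares of cells with a UMI, summed list levels and cell cycle phases, each cell was thinned at random to 3000 UMIs, and cells below that total were left out. Phases came from the scanpy scoring of the S and G2M lists. The 50 most abundant genes and the ribosomal, mitochondrial and haemoglobin genes were removed in 1 alternative scaling.

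The samples, comparisons, gene lists, naming rule for genes and the main set of alternatives were fixed before the data were examined. The alternatives fixed then were looser (500 UMIs, 200 genes, 20% mitochondrial) and stricter (3000 UMIs, 1500 genes, 5%) filters and no doublet removal. Clustering without list genes left out the S phase, G2M phase, MLL-fusion target, lymphoid priming and B-lineage priming lists. Further alternatives were resolutions 0.5 and 2.0, classes from a marker score per cell, and classes of the nearest Control cell. They also covered 2 other scalings, mean CPM per cell, thinning, a pseudocount of 5, no floor for list members, all barcodes or all kept cells for Skida1, another antibody scaling and no thinning per cell. Chosen after the data were seen were expected-rate doublet removal in all 3 libraries, shares of named cells only, nearest-Control classes and G1 cells for expression, HSPC-like and granulocyte progenitor-like cells summed as 1 class, the B-lineage list without Bcl11a and Tcf3, and the unnamed low-depth cluster counted as erythroid-like. The calculation was tested on simulated counts with the depth of the HSPC-like cells of the MLL-ENL and Skida1-deleted libraries, in which 200 of 32285 genes were changed by 2-fold or 0.5-fold. Counts were drawn as Poisson, the model of the intervals, without differences between cells or libraries, so coverage tests the code only. Changed genes had a CPM of at least 30 in MLL-ENL. Among genes with at least 50 UMIs the 95% intervals covered the true fold for 95.7%. The sign was recovered for 100% of changed genes, and a list of genes raised 2-fold had a median log2 ratio of 0.98 at percentile 100. A list of unchanged genes had a median of −0.02 at percentile 32.9. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9.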

Results

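The study asked what the gene Skida1 does in blood progenitors that express the leukemia fusion MLL-ENL shortly after birth. RNA and 10 surface antibody tags were counted in lineage-negative, KIT-positive liver cells of postnatal day 0 mice. The 3 groups had 1 library each: Control, MLL-ENL, and MLL-ENL with Skida1 deleted. After filtering they held 5386, 10154 and 9404 cells, with medians of 28013, 14704.5 and 17299 UMIs per cell. The class nearest to stem and multipotent progenitors (HSPC-like) held 1138, 876 and 1044 cells and 18980427, 6848960 and 6823921 UMIs. Every value below therefore stands for 1 library, and the brackets cover counting error only.

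Skida1 (ENSMUSG00000054074), which encodes a protein linked to Polycomb complexes, lies on chromosome 2 from 18044087 to 18048449 in GRCm38.p6. In HSPC-like cells it had 18 UMIs in Control, or 0.948 CPM [0.562–1.5], against 173 UMIs and 25.3 CPM [21.6–29.3] in MLL-ENL. It was thus 26.6-fold higher in MLL-ENL [16.4–46.0]. The Skida1-deleted library had 24 UMIs, or 3.52 CPM [2.25–5.23], which was 7.18-fold lower than MLL-ENL [4.67–11.5] and 3.71-fold higher than Control [1.93–7.25]. With classes from a marker score per cell it was 9.89-fold higher in MLL-ENL and 1.24-fold higher in the deleted library than in Control, and with classes of the nearest Control cells 1.76-fold higher in the deleted library. Over all kept cells Skida1 had 0.230, 4.82 and 0.505 CPM in Control, MLL-ENL and the Skida1-deleted library. Granulocyte progenitor-like cells had 1 UMI in Control (0.101 CPM [0.00256–0.563]), 178 UMIs in MLL-ENL (10.1 CPM) and 20 UMIs in the deleted library (0.918 CPM). Erythroid-like cells had 0.116, 2.25 and 0.208 CPM. The deleted part of the gene is not given in the sources used here, and a 3' tag outside that part would not report the deletion.

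Kmt2a, the mouse gene of the MLL part of the fusion, had 113 CPM [108–118] in Control HSPC-like cells and 181 CPM [171–192] in MLL-ENL, a fold of 1.61 [1.5–1.72]. The Skida1-deleted library had 187 CPM, 1.03-fold the MLL-ENL level [0.952–1.11]. With classes taken from a marker score per cell, the log2 ratio of Kmt2a in the deleted library over Control was −0.02 in place of 0.72. Erythroid-like cells had 67.8 CPM of Kmt2a in Control and 55.9 in MLL-ENL, a fold of 0.824 [0.798–0.851]. Mllt1, the gene of the ENL part, had 13.5, 14.3 and 10.7 CPM in HSPC-like cells, with a fold of 1.06 [0.832–1.34] in MLL-ENL over Control and 0.748 [0.544–1.02] in the deleted library over MLL-ENL. Whether the fusion transcript adds to either gene's count could not be read from 3' tags.

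**Figure D1:**
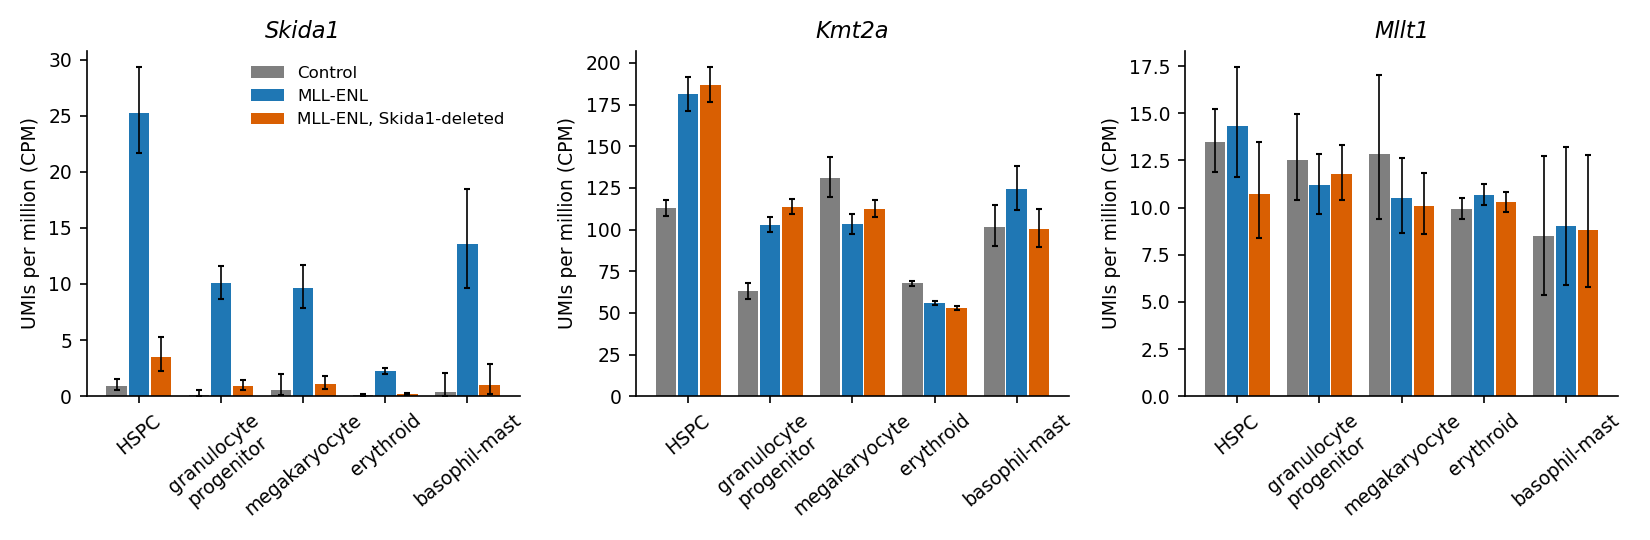
Bars show CPM of Skida1, Kmt2a and Mllt1 in 5 classes of cells in the 3 libraries, with 95% exact Poisson intervals of the counts as error bars. Skida1 reached 25.3 CPM in HSPC-like cells of MLL-ENL, against 0.948 in Control and 3.52 in the Skida1-deleted library.

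The composition of the sorted gate was compared first. HSPC-like cells made up 21.1% of kept cells in Control [20.05–22.2], 8.63% in MLL-ENL [8.09–9.19] and 11.1% in the Skida1-deleted library [10.5–11.8]. The direction of this share against Control was not stable, as given below. Granulocyte progenitor-like cells made up 7.22%, 11.1% and 17.2%, megakaryocyte-like cells 3.49%, 6.55% and 11.4%, and erythroid-like cells 63.6%, 44.4% and 55.2%. Basophil-mast-like cells made up 3.23%, 2.30% and 2.76%, and B-lineage-like cells 0.817% [0.594–1.10], 0.886% [0.713–1.09] and 1.04% [0.847–1.27]. With classes from a marker score per cell the B-lineage-like shares lay further apart, and MLL-ENL had the highest. Clusters with no class held 0.557%, 26.1% and 1.36%. In MLL-ENL most of these were 1 low-depth cluster with a median of 4065.5 UMIs, which lowers every other share of that library.

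Among cells of named classes the megakaryocyte-like share was 3.51% in Control, 8.86% in MLL-ENL and 11.5% in the Skida1-deleted library, and the granulocyte progenitor-like share was 7.26%, 15.03% and 17.4%. The erythroid-like share was 63.9%, 60.1% and 56.0%, so that the deleted library was 0.931-fold MLL-ENL in place of 1.24-fold among kept cells. The direction of the erythroid-like share in MLL-ENL over Control, 0.699-fold among kept cells, was not stable. It was 1.08-fold with the low-depth cluster counted as erythroid-like and 1.16-fold with classes of the nearest Control cells. For basophil-mast-like cells, 0.713-fold among kept cells, it was 1.51-fold under the strict filter, 1.16-fold with classes from a marker score and 1.24-fold with doublets removed at the expected rate in all libraries. The HSPC-like share on this base was 21.2%, 11.7% and 11.3%, so that the deleted library was 0.964-fold the MLL-ENL share [0.880–1.06] in place of 1.29-fold among kept cells. The Control HSPC-like cells lay almost wholly in a different cluster (1129 of 1138 cells) from those of MLL-ENL (836 of 876) and of the deleted library (1025 of 1044). Granulocyte progenitor-like cells also came from different clusters, 1 of which held 362 of the 389 Control cells. HSPC-like and granulocyte progenitor-like cells together made up 28.5%, 26.7% and 28.7% of named cells. Clusters were also made without the cell cycle, MLL-fusion target and priming genes. The shares of kept cells were then 21.2%, 12.9% and 17.9% for HSPC-like cells. They were 8.35%, 6.75% and 10.3% for granulocyte progenitor-like, and 2.06%, 3.12% and 5.77% for megakaryocyte-like cells. At the lower clustering resolution, HSPC-like cells were 0.743%, 14.5% and 19.8% and granulocyte progenitor-like cells 27.8%, 5.46% and 8.88%. The line between both classes in Control thus depended on the clustering. Under the strict filter, with 21 HSPC-like cells in Control, the HSPC-like shares were 0.784%, 4.22% and 8.03%. Both fusion libraries then lay above Control. Classes of the nearest Control cells gave 21.1%, 17.7% and 25.4%, so that only the deleted library lay above Control. In the remaining alternatives the HSPC-like share of both fusion libraries stayed below Control. With classes of the nearest Control cells the MLL-ENL over Control ratio of the megakaryocyte-like share was 0.824, in place of 1.88 among kept cells, and that of the granulocyte progenitor-like share 0.269, in place of 1.54. With the marker score the granulocyte progenitor-like share of the deleted library was 0.806-fold that of MLL-ENL, in place of 1.55-fold. The shares describe the sorted gate, and the libraries differed in depth.

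**Figure D2:**
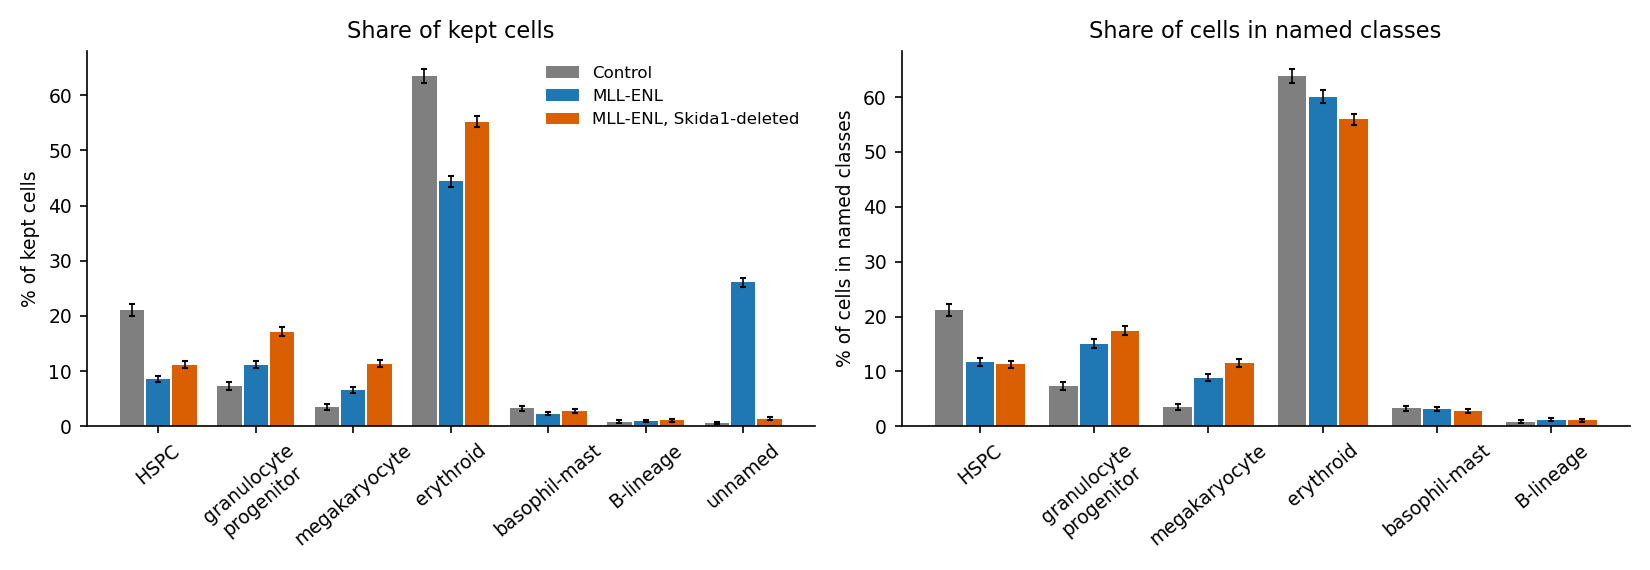
Bars show the share of kept cells (left) and of cells in named classes (right) per class in the 3 libraries, in percent, with exact binomial 95% intervals as error bars. Clusters with no class held 26.1% of kept cells in MLL-ENL and 1.36% in the Skida1-deleted library.

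The fusion was examined in HSPC-like cells of MLL-ENL against Control. Among the genes higher in MLL-ENL were Mecom and genes of the HoxA cluster. Mecom, a stem-cell transcription factor, had 38.6 CPM in Control and 259 in MLL-ENL, a fold of 6.73 [6.17–7.34]. Hoxa5 and Hoxa3, homeobox factors of the HoxA cluster, were 7.01-fold [5.93–8.32] and 6.08-fold [4.92–7.53] higher. The lowest log2 ratios included genes of cell division and the protease gene Ctsg, with 494 CPM in Control and 10.8 in MLL-ENL (45.7-fold lower [36.4–58.3]).

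Of 5026 genes eligible for naming, the 12 with the highest ratios also held Pcdh7, a cell adhesion protocadherin (35.5 against 383 CPM, 10.8-fold), and Meg3, an imprinted noncoding RNA (15.3 against 131 CPM, 8.58-fold). Fxyd1, a sodium pump regulator, was 9.88-fold higher, and Hopx, a homeodomain cofactor of quiescent stem cells, was 6.30-fold higher. Lst1, a leukocyte immune regulator, was 5.33-fold higher, Bend4, a BEN-domain gene, 6.13-fold, and Ddx4, a germ cell helicase, 5.64-fold. Tpm3-rs7 (12.1-fold), a near copy of Tpm3, and Hist3h2ba (5.71-fold), a histone gene, share sequence with related genes and are uncertain. Mecom and Meg3 were among the genes that defined the cluster of the MLL-ENL cells. When clusters were made without the list genes, their log2 ratios were 1.98 and 2.18 in place of 2.72 and 3.02. Only Mecom was on the lists left out, so the value of Meg3 does not address its part in the clustering.

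The 12 lowest genes held mitotic factors: Ckap2l, a spindle protein (42.8 against 2.19 CPM, 19.5-fold lower), Pimreg, a mitotic regulator (17.7-fold), Hmmr, a spindle assembly factor (14.5-fold), Nusap1, which bundles spindle microtubules (14.1-fold), and Pbk, a mitotic kinase (14.0-fold). Tpx2, Birc5 and Kif11, which act on the spindle and chromosomes, were 13.8-fold, 12.7-fold and 12.5-fold lower. Elane, neutrophil elastase, was 19-fold lower (33.2 against 1.75 CPM). The histone genes Hist1h1b (1842 against 52.1 CPM) and Hist1h3c (152 against 6.86 CPM) were also lower, but members of their clusters share reads. Among cells called G1, the log2 ratios of Nusap1, Hmmr, Pimreg, Birc5, Pbk and Kif11 turned to 0.63, 0.17, 0.30, 0.33, 0.82 and 0.23. The G1 call rests on such genes, so this restriction selects cells low in them in every library.

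Of 27 measured MLL-fusion targets, 17 were at least 1.5-fold higher in MLL-ENL and 0 lower. Their median log2 ratio was 0.92 at percentile 100 of matched random lists. With HSPC-like and granulocyte progenitor-like cells summed, 12 of 26 were higher and 0 lower (median 0.50). In HSPC-like cells the higher targets included Skida1 (3.75) and Hoxa10 (2.10). All 8 measured HoxA genes were at least 1.5-fold higher, with a median of 1.93. Of 21 genes of the granulocyte-monocyte program, 11 were lower and 0 higher (median −1.19), including Elane (−3.64, but 0.44 with the marker score) and Cebpe, a granulocyte transcription factor (−2.54). Of 52 G2M genes 47 were lower (median −2.41, but 36 and −0.88 with HSPC-like and granulocyte progenitor-like cells summed). Of 43 S phase genes 38 were lower (median −1.30, but 14 and −0.41 in that sum), including the nucleotide synthesis gene Rrm2 (−2.79). Of 25 MYC and ribosome biogenesis genes 18 were lower (median −0.70), including Srm, which makes spermidine (−2.33), and Myc (−1.48), but with classes from a marker score the median was 0.04.

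Of 13 measured lymphoid priming genes, 8 were at least 1.5-fold higher in MLL-ENL and 2 lower (median 0.75, percentile 100, but −0.28 under the strict filter, which left 21 HSPC-like cells in Control). Mef2c, a lymphoid transcription factor, had a log2 ratio of 1.52, Tcf4, a dendritic and B cell factor, 1.05, and Cd52, a lymphocyte antigen, 0.95. The HSPC-like classes were composed differently, since the higher clustering resolution set apart 15 lymphoid progenitor-like cells in Control and 415 in MLL-ENL. Within these the list summed, per thinned cell, to 1.07 times the Control level [0.915–1.27]. Their median CD127 counts were 28 in Control and 6 in MLL-ENL, so these were not like cells. With HSPC-like and granulocyte progenitor-like cells summed the median was 0.23, with 3 of 13 genes higher. Of 10 B-lineage priming genes 5 were higher and 0 lower (median 0.68, percentile 99.2), including Irf4 (1.87), Foxo1 (1.29), Ebf1 (1.14) and Cd72 (1.01, but −0.32 under the strict filter). Ebf1 had −0.29 with no doublet removal, −1.06 under the strict filter and −0.94 in G1 cells. The median turned to −0.03 with every cell thinned to 3000 UMIs and to −0.31 with classes from a marker score, so its direction was not stable. Of 14 genes of the fetal-neonatal program, 8 were higher and 1 lower (median 0.90), led by the growth factor Igf2 (2.37) and the RNA-binding fetal regulator Lin28b (1.81). With HSPC-like and granulocyte progenitor-like cells summed, 3 of 11 were higher and 1 lower (median 0.16). Of 17 HSC program genes 7 were higher and 4 lower (median 0.49, but of the other direction in 5 of 15 alternatives and −0.59 with classes of the nearest Control cells), including Hlf, a stem-cell factor (2.38-fold, but a log2 ratio of −0.03 with the marker score).

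Of 29 interferon response genes 3 were higher and 1 lower (median 0.30), but the median was −0.67 with the marker score. Of 11 MHC class I genes 2 were higher and 2 lower (median −0.19), and of 16 immediate early genes 6 were higher and 1 lower (median 0.32, but −0.27 with the marker score). Egr1, an immediate early factor, had 3.27 CPM in Control and 22.8 in MLL-ENL. Of 17 cholesterol synthesis genes 8 were lower and 1 higher (median −0.43), and of 9 heat shock genes 5 were lower (median −0.59). Of 5 mast-basophil-eosinophil genes 2 were higher and 3 lower (median −0.85, of the other direction in 7 of 15 alternatives), including the mast cell protease genes Cpa3 (−3.28, but 1.66 under the strict filter) and Mcpt8 (20.7-fold lower [6.96–101], 3 UMIs in MLL-ENL, but log2 ratios of 0.62 under the strict filter and 1.17 with the marker score).

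The effect of deleting Skida1 was examined in HSPC-like cells of the Skida1-deleted library against MLL-ENL, where differences were smaller. The sex of the cells differed as well. Ddx3y, on the Y chromosome, had 57.2 CPM over all kept cells of the deleted library and 0 UMIs in both others, and Xist, the RNA of the inactive X chromosome, had 643, 1039 and 2.09 CPM in Control, MLL-ENL and the deleted library. The SD of the log2 ratio over 4838 genes was 0.31, against 0.75 over 5245 genes for MLL-ENL over Control. Eya1, a phosphatase and transcription cofactor and an MLL-fusion target, had 30.7 CPM in MLL-ENL and 62.3 in the deleted library, a fold of 2.03 [1.72–2.41]. Rpa3, a subunit of the single-strand DNA binding complex, had 41.3 against 13.8 CPM and was 3.0-fold lower [2.37–3.83]. Tnfaip2, a cytokine-induced gene, was 2.13-fold higher [1.71–2.67], and Ifit1, an interferon-induced antiviral gene, was 1.72-fold lower [1.44–2.06].

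Of 4613 eligible genes, the 12 highest also held Gpr65, a proton-sensing receptor (1.95-fold), Smim27, a small membrane protein (2.07-fold), Eif3j1, a translation initiation subunit (1.88-fold), and Phactr4, an actin and phosphatase regulator (1.79-fold). Atp5k (1.93-fold), Pet100 (1.93-fold) and Ndufa3 (1.81-fold) serve the mitochondrial respiratory chain. The histone genes Hist1h4h (2.52-fold), Hist1h4d (2.05-fold) and Hist1h1d (2.01-fold) are uncertain for shared reads. The 12 lowest also held Sdhd, a subunit of complex II (2.09-fold lower), Mrps28, a mitochondrial ribosomal gene (2.05-fold), the small RNA hosts Snhg9 (1.98-fold) and Snhg6 (1.91-fold), and Usf1, a transcription factor (1.90-fold). Eif2s3x, a translation factor on the X chromosome, was 1.75-fold lower, Med31, a Mediator subunit, 1.74-fold, and Irgm1, an interferon-induced GTPase, 1.70-fold. H2-T23 (185 against 82.1 CPM) and H2-T22 (44.1 against 25.1 CPM), nonclassical MHC class I genes, belong to a family of related sequences and are uncertain.

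All 24 of these genes had the same direction with a log2 ratio of at least 0.32 in size in granulocyte progenitor-like, megakaryocyte-like and erythroid-like cells, and 21 did in basophil-mast-like cells. Among 4613 eligible genes, 9.17%, 10.8%, 8.06% and 17.7% met that criterion in these classes. The genes named for this contrast therefore set the whole libraries apart and were not particular to HSPC-like cells.

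**Figure D3:**
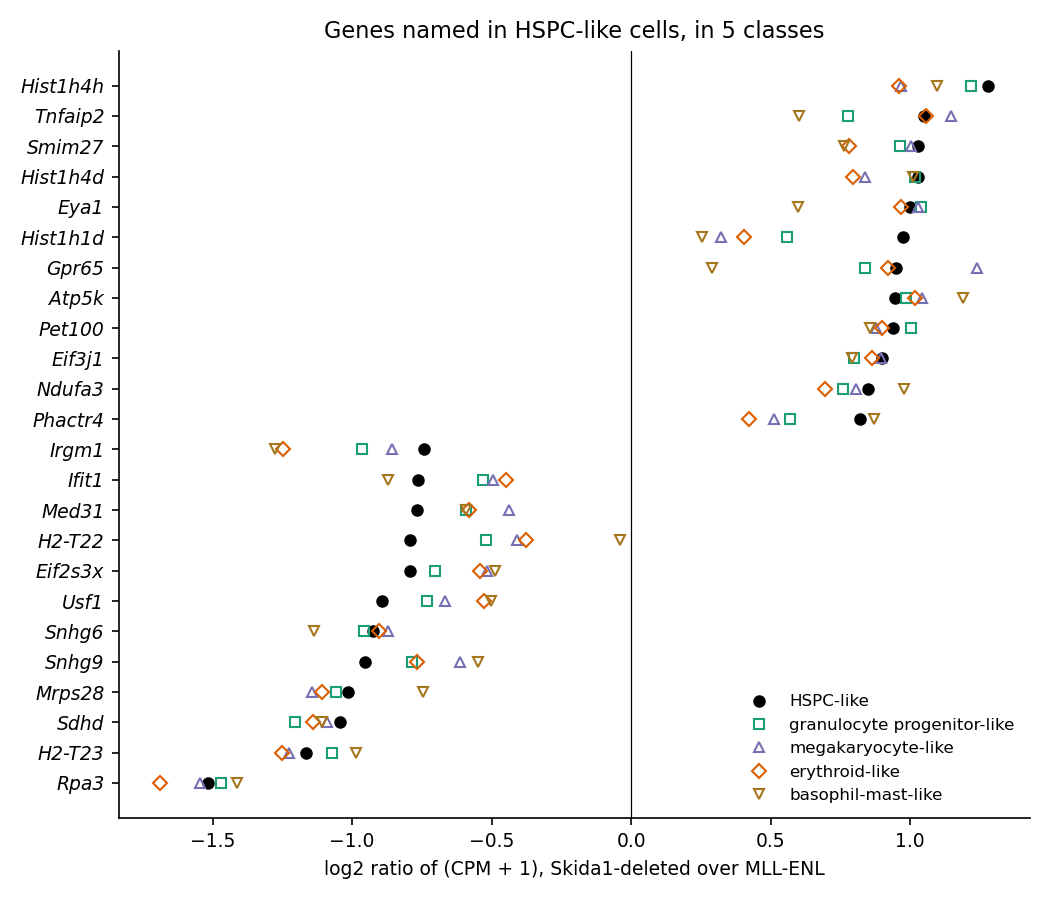
Points show the log2 ratio of (CPM + 1) in the Skida1-deleted library over MLL-ENL for the 24 genes named in HSPC-like cells, in 5 classes of cells, 1 value per class. Rpa3 had −1.52 in HSPC-like and −1.69 in erythroid-like cells.

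Of 10 measured B-lineage priming genes 0 had a log2 ratio above 0 in the Skida1-deleted library over MLL-ENL, 3 were at least 1.5-fold lower, and the median was −0.36 (percentile 0.02). With no doublet removal the median was −0.056. With HSPC-like and granulocyte progenitor-like cells summed it was −0.15, with 0 of 8 genes 1.5-fold lower. Per thinned lymphoid progenitor-like cell the list sum was 1.01-fold MLL-ENL [0.930–1.10]. At the higher clustering resolution MLL-ENL had 415 lymphoid progenitor-like and 462 HSPC-like cells, and the deleted library 420 and 602. The HSPC-like classes were thus composed differently here too. In MLL-ENL the list summed to 852 CPM per thinned lymphoid progenitor-like cell, against 678 CPM per HSPC-like cell. Irf4, a B cell transcription factor, had a log2 ratio of −0.91, Il7r, the interleukin 7 receptor, −0.77, Bach2, a B cell repressor, −0.75, and Ebf1, the early B cell factor, −0.50. Il7r had 0.15 with no doublet removal, and among G1 cells Ebf1 had 0.09. Of 13 lymphoid priming genes 1 was lower and 0 higher (median −0.10). All 11 measured MHC class I genes had a log2 ratio below 0 (median −0.45, percentile 0), including H2-D1 (−0.54) and B2m, the shared light chain (−0.51). The MHC class I median was also below 0 in granulocyte progenitor-like (−0.38), megakaryocyte-like (−0.48) and erythroid-like cells (−0.41).

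MLL-fusion targets differed little between both fusion libraries, with 1 of 27 higher, 1 lower and a median of 0.04. Besides Eya1 these held Skida1 itself (−2.54), the homeobox partner Pbx3 (0.58, but −0.09 with the marker score) and Mecom (0.42). Of 8 HoxA genes 0 were 1.5-fold different (median −0.20), including Hoxa3 (−0.43) and Hoxa5 (−0.35). MYC and ribosome biogenesis genes had a median of 0.14 (percentile 99.8, but −0.035 under the strict filter), with 18 of 25 above 0, including the nucleolar genes Wdr43 (0.75) and Nolc1 (0.62), while Myc had −0.50. Of 14 fetal-neonatal genes 1 was lower and 0 higher (median −0.13), with Lin28b at 0.58. The granulocyte-monocyte program had 1 of 15 genes lower (median −0.14), the HSC program 0 of 17 different (median 0.10), and the G2M and S phase lists medians of 0.09 and −0.02. Among immediate early genes 2 of 16 were higher and 1 lower (median −0.03), including Fos (1.10), Egr1 (0.77, but −0.19 with the marker score) and Btg2, an antiproliferative gene (−0.74).

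**Figure D4:**
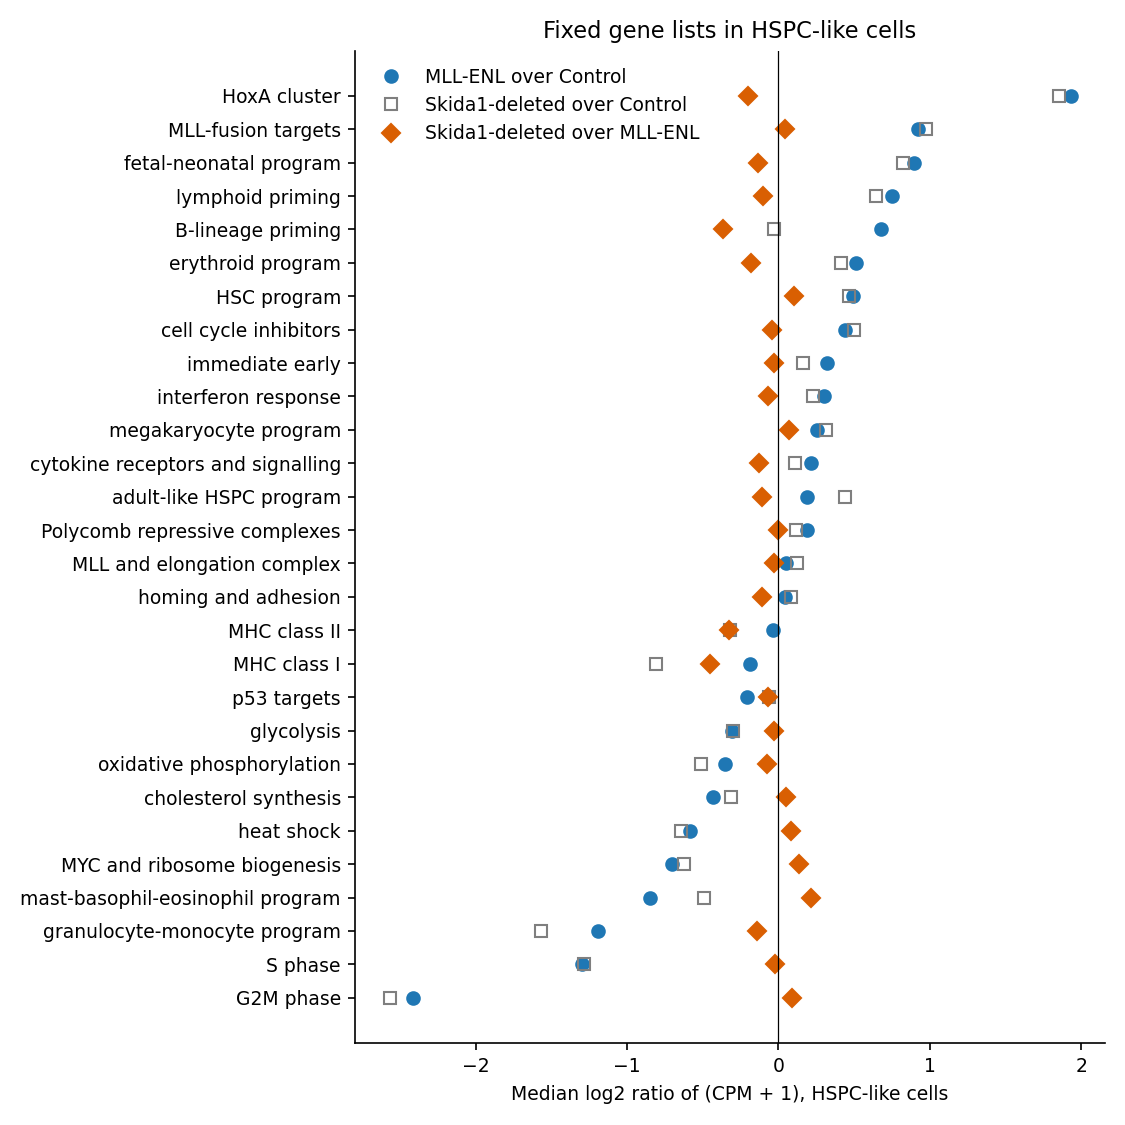
Points show the median log2 ratio of (CPM + 1) of 28 gene lists in HSPC-like cells, 1 symbol per contrast of libraries. MLL-ENL over Control ranged from −2.41 for the G2M phase to 1.93 for the HoxA cluster, and the Skida1-deleted library over MLL-ENL from −0.45 for MHC class I to 0.21 for the mast list.

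The Skida1-deleted library was then set against Control, to see on which side of MLL-ENL its values lay. Gdpd3, a lipid phosphodiesterase, had 0.738 CPM in Control and 30.6 in the deleted library, 41.5-fold higher [24.2–77.3]. Mecom was 9.02-fold higher [8.30–9.82], Pcdh7 12-fold, Lst1 8.47-fold, Meg3 7.86-fold and Fxyd1 10.7-fold, as many or more fold as in MLL-ENL except for Meg3. Egr1 was 12.1-fold, Tnfaip2 12.8-fold, Lin28b 5.46-fold and the metal-binding gene Mt2 5.47-fold higher. Bend4 was 6.51-fold higher, and Tpm3-rs7, uncertain as above, 10.6-fold. Ctsg was 37.9-fold lower (494 against 13 CPM, but a log2 ratio of 0.57 under the strict filter).

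The lowest genes again held division genes: Nuf2, of the kinetochore (35.3-fold lower [16.1–96.6], 6 UMIs in the deleted library), Pimreg (33.0-fold), Bub1, of the spindle checkpoint (21.3-fold), Aurkb and Plk1, mitotic kinases (20.4-fold and 17.3-fold), and Esco2, of chromatid cohesion (17.0-fold). Pbk, Nusap1 and Hmmr were 16.1-fold, 15.3-fold and 15.2-fold lower. Among G1 cells, selected as above, the log2 ratios of Nuf2, Pimreg, Bub1, Aurkb, Plk1, Esco2, Pbk, Nusap1 and Hmmr were 0.08, 0.28, 0.99, 0.11, 0.67, 0.55, 0.43, 0.38 and 0.77. Hist1h1b (33.2-fold lower) and Hist1h3c (23.6-fold, but a log2 ratio of 0.28 with the marker score) are uncertain histone genes. With classes from a marker score the log2 ratio of Mecom was 1.23 in place of 3.14, and that of Hlf was −0.17 in place of 1.39. Cpa3 had a log2 ratio of −3.24, but 1.89 under the strict filter.

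Of 26 MLL-fusion targets 16 were higher and 0 lower than in Control (median 0.97), including Hoxa5 (2.34), Eya1 (1.92) and Mef2c (1.88), and all 8 HoxA genes were higher (median 1.85). The granulocyte-monocyte program had 13 of 21 genes lower (median −1.57), including Elane (−3.42, but 0.68 with classes of the nearest Control cells). B-lineage priming had 4 of 9 genes higher and 1 lower (median −0.03, percentile 38.8), including Foxo1 (1.22), Bcl11a (0.76) and Il7r (−0.69). Bcl11a turned to −0.38 under the strict filter. Lymphoid priming had 7 of 13 higher and 3 lower (median 0.65). The fetal-neonatal program had 7 of 13 higher and 1 lower (median 0.82, but −0.07 with classes of the nearest Control cells). MHC class I had 7 of 11 genes lower and 1 higher (median −0.81), against −0.19 in MLL-ENL, including H2-T23 (−1.18, uncertain as above). MYC and ribosome biogenesis had 15 of 25 lower (median −0.63, but 0.17 with the marker score), including Myc (−1.98). The G2M and S phase medians were −2.57 and −1.28, with 47 and 38 genes lower. With HSPC-like and granulocyte progenitor-like cells summed they were −0.75 and −0.39, with 31 and 14 genes lower.

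B-lineage priming was also read per cell, with each cell thinned to 3000 UMIs. This left out 2 HSPC-like cells in Control, 1 in MLL-ENL and 18 in the deleted library, and 33, 91 and 260 erythroid-like cells. Before thinning the HSPC-like medians were 15167, 7140.5 and 6118 UMIs and the erythroid-like medians 34615, 28934 and 26452. Ebf1 was seen in 1.67% of Control, 2.40% of MLL-ENL and 1.46% of Skida1-deleted HSPC-like cells (3.6%, 4.0% and 2.78% unthinned), against 0.0295%, 0.113% and 0.0406% of erythroid-like cells. Irf4 was seen in 0.440%, 2.17% and 0.975% of HSPC-like cells against 0 of 3390, 4420 and 4931 erythroid-like cells, where the upper limits for detection at this depth were 0.109%, 0.0834% and 0.0748%. Il7r was seen in 3.26%, 2.86% and 2.34% of HSPC-like cells (8.70%, 4.68% and 3.16% unthinned), against 0.0590% [0.00715–0.213], 0.0452% [0.00548–0.163] and 0.0203% [0.000513–0.113] of erythroid-like cells, from 2, 2 and 1 cells.

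The 25 genes of the list summed to 542, 678 and 637 CPM per thinned HSPC-like cell (477, 689 and 615 unthinned), against 328, 329 and 308 CPM in erythroid-like cells. MLL-ENL was 1.252-fold Control [1.17–1.34], and the deleted library was 0.939-fold MLL-ENL [0.880–1.0]. In granulocyte progenitor-like, megakaryocyte-like and erythroid-like cells the deleted library was 0.928-fold, 0.943-fold and 0.937-fold MLL-ENL, and in basophil-mast-like cells 1.09-fold. The lower sum of the full list was thus not particular to HSPC-like cells. Bcl11a and Tcf3, a pair also present in erythroid-like cells, made up much of the sum in HSPC-like cells. Without them HSPC-like cells had 214, 204 and 175 CPM, so that MLL-ENL was 0.953-fold Control [0.851–1.07], and the deleted library was 0.859-fold MLL-ENL [0.761–0.970] and 0.819-fold Control [0.731–0.917]. Erythroid-like cells then had 14.2, 11.4 and 12.5 CPM. Without the pair the deleted library was 0.909-fold MLL-ENL in granulocyte progenitor-like and 0.999-fold in megakaryocyte-like cells. It was 1.10-fold in erythroid-like and 1.16-fold in basophil-mast-like cells. Lymphoid priming genes summed to 2139, 3083 and 3246 CPM (1968, 3077 and 3180 unthinned), against 466, 498 and 495 in erythroid-like cells. MLL-ENL was 1.44-fold Control [1.40–1.49], and the deleted library was 1.05-fold MLL-ENL [1.02–1.08]. The rise was not particular to HSPC-like cells. In granulocyte progenitor-like cells MLL-ENL was 1.55-fold Control [1.46–1.65], and the deleted library was 1.06-fold MLL-ENL. MLL-ENL was 1.02-fold Control in megakaryocyte-like and 1.03-fold in basophil-mast-like cells.

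**Figure D5:**
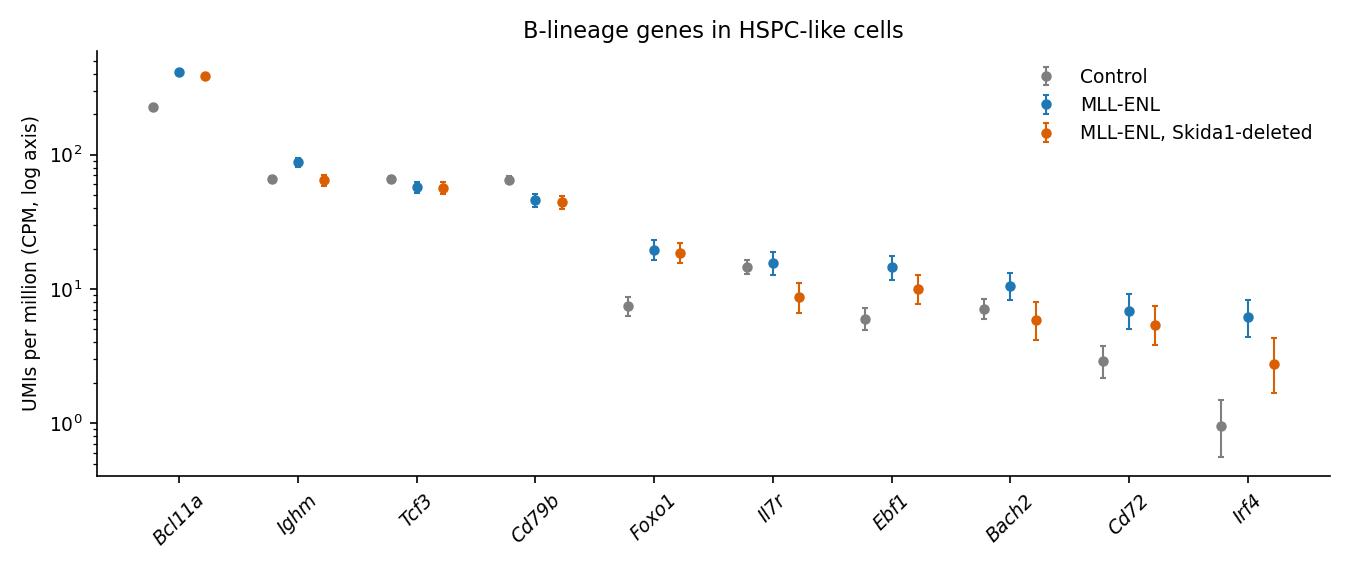
Points show CPM of B-lineage priming genes in HSPC-like cells of the 3 libraries on a log axis, with 95% exact Poisson intervals as error bars. Ebf1 had 6.01 CPM in Control, 14.5 in MLL-ENL and 9.96 in the Skida1-deleted library.

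Cell cycle phases were called from thinned cells. In HSPC-like cells 73.8% of Control [71.1–76.3], 25.5% of MLL-ENL [22.6–28.5] and 24.5% of Skida1-deleted cells [21.9–27.2] were called S or G2M (73.3%, 17.4% and 15% unthinned). Granulocyte progenitor-like cells had 94.5%, 79.6% and 82.4%, megakaryocyte-like cells 94.5%, 91.0% and 89.0%, and erythroid-like cells 97.0%, 95.8% and 97.0%. Basophil-mast-like cells had 67.8%, 54.9% and 66.0%. Free RNA from other cells also enters such calls, so that its part in the difference stays open, and the HSPC-like cells came from different clusters in Control and in the fusion libraries.

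Against Control, surface tags of HSPC-like cells differed most for CD34, a progenitor antigen. Its median centred log ratio was 0.87 in Control, −0.37 in MLL-ENL and −0.20 in the deleted library. Sca-1, a stem-cell antigen, had 2.09, 2.48 and 2.41. CD135 (FLT3, a cytokine receptor) had −1.48, −1.16 and −1.29, and CD150, a stem-cell marker, −1.44, −1.12 and −1.19. Their median counts did not rise, with 10, 10 and 7 for CD135 and 11, 10 and 8 for CD150. The centred CD135 value was also higher in MLL-ENL than in Control in each other class. That difference ran from 0.15 in granulocyte progenitor-like to 0.55 in megakaryocyte-like cells. With the other antibody scaling it was −0.04 and 0.33 in these classes. CD117 (KIT) had 1.89, 2.09 and 2.20, CD41 (integrin of platelets) −2.06, −1.78 and −1.66, and CD48, a leukocyte antigen, 3.84, 3.6 and 3.77. Median counts of CD117 (338, 285 and 280) and CD41 (6, 5 and 5) did not rise either. CD16/32 (Fc receptors) had −0.32, −0.39 and −0.57, and CD127, the interleukin 7 receptor, −1.77, −1.70 and −1.83. CD201 (the protein C receptor) had −1.65, −1.62 and −1.69. Median antibody totals were 3370, 2240.5 and 2135 counts per HSPC-like cell, and staining was done per library. Under the other antibody scaling 18 differences between libraries in HSPC-like cells moved, 12 stayed and 0 turned. CD41 in MLL-ENL over Control was then 0.14 in place of 0.27. CD34 in the deleted library over MLL-ENL was 0.06 in place of 0.17.

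In granulocyte progenitor-like cells Mecom had 1.52 CPM in Control and 36.7 in MLL-ENL (24.2-fold higher [14.6–43.5]), Pcdh7 was 24-fold and Ctla2a, a protease inhibitor, 8.39-fold higher. The antigen presentation genes Cd74 (381 against 7.63 CPM), H2-Eb1 (131 against 2.32) and H2-Aa (191 against 7.06) were lower. The MHC class II list had 5 genes lower and 0 higher in this class (median −3.66), and the HoxA list a median of 2.01. At the higher clustering resolution monocyte-dendritic-like cells were 3.77% of kept cells in Control, 0.591% in MLL-ENL and 0.404% in the deleted library. They numbered 203 in Control and 60 in MLL-ENL. The granulocyte progenitor-like class went from 389 to 183 cells in Control and held 1128 cells at both resolutions in MLL-ENL. The MHC class II values of this class therefore compare cells of different composition. S100a8 and S100a9, calprotectin genes of neutrophils, were 4.11-fold [3.89–4.35] and 2.85-fold [2.73–2.98] higher in granulocyte progenitor-like cells of the deleted library than of MLL-ENL, and Cstdc5, a cystatin gene, was 3.44-fold higher.

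Megakaryocyte-like cells of MLL-ENL had less of the platelet genes Thbs1, a thrombospondin (44.2 against 6.56 CPM), Clec1b, a podoplanin receptor (53.7 against 9.93), and Mrvi1, a calcium signalling gene (110 against 15.6), and more Mt2 (15.5 against 137). Of 12 megakaryocyte program genes 6 were lower and 0 higher (median −0.63). Erythroid-like cells of MLL-ENL had 9.54-fold more Hoxa9, a homeobox factor (3.75 against 35.7 CPM), and less of the beta globin gene Hbb-bs (181 against 42.8) and of Lyl1, a blood transcription factor (65.6 against 17.0). Of 18 erythroid program genes 10 were lower (median −0.63). Basophil-mast-like cells of MLL-ENL had less Tph1, which makes serotonin (178 against 10.1 CPM), and less of the mast cell protease gene Mcpt4 (48.7 against 2.43). In the deleted library they had less of the tryptase gene Tpsb2 than in MLL-ENL (64.8 against 297 CPM) and more Hk2, a glycolysis gene (70.6 against 26.7), and 4 of 10 mast list genes were lower (median −0.56). Over all kept cells Irf8, a monocyte and dendritic cell factor, had 30.4, 5.29 and 3.66 CPM in Control, MLL-ENL and the deleted library. The clusters of granulocyte progenitor-like and erythroid-like cells differed between Control and the fusion libraries, so these values compare differently composed classes.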

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

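The tests of the low-depth cells by their share in the Skida1-deleted library and by the odds of marker pairs were chosen only after their results were seen, as were the summed class and the G1 cells used for the granulocyte-monocyte list. The odds took the place of a test fixed earlier, the observed over the expected share of cells with both marker sets. That ratio was 0.995 in the low-depth cells but could not have fallen below 0.897, so it decided nothing, and the bounds for the odds were set with their value known.

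Clusters with no class held 26.1% of kept cells in MLL-ENL, against 0.557% in Control and 1.36% in the Skida1-deleted library. This signal lay outside the compared classes and above its level in Control. Ddx3y, a gene of the Y chromosome left out of the named genes, had 57.2 CPM over all kept cells of the deleted library and 0 UMIs in Control and in MLL-ENL. Xist, the RNA of the inactive X chromosome, had 643, 1039 and 2.09 CPM in Control, MLL-ENL and the deleted library. The deleted library thus came from male cells almost throughout and the other libraries from female cells, so that sex could not be separated from the deletion.

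For 3 results MLL-ENL differed from Control in opposite directions in 2 classes. Kmt2a had a fold of 1.61 in HSPC-like and 0.824 in erythroid-like cells. The erythroid program had medians of 0.51 in HSPC-like and −0.63 in erythroid-like cells. Immediate early genes had medians of 0.32 and −0.90 in these classes. The HSPC-like medians were not stable, since the erythroid program turned in 3 of 15 alternatives (−0.18 with classes of the nearest Control cells) and the immediate early genes in 6 (−0.46 under the strict filter). The Kmt2a fold in HSPC-like cells turned in 0 of 14. The differences between the classes were not tested, and no explanation was weighed for them.

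Most unnamed cells of MLL-ENL lay in 1 cluster of 2510 cells of that library, with a median of 4065.5 gene UMIs and 452 antibody counts, against 2174 antibody counts in its named cells. Nuclear RNAs stood at 1.16 times their level in named cells, which argues against nuclei or cells that lost their cytoplasm. The share of this cluster in the Skida1-deleted library was 0.0400 times that in MLL-ENL, which argues against an effect of the fusion in both libraries that carry it. The odds ratio of carrying erythroid and granulocyte progenitor markers was 0.870 [0.628–1.2], near independence, against 0.134 [0.109–0.164] in named cells. The summed profile had a correlation of 0.991 with all named cells of the library and 0.970 with its erythroid-like cells. Erythroid and granulocyte progenitor markers each stood at 1.07 times their level in named cells. HSPC markers stood at 0.866, megakaryocyte markers at 0.789 and basophil-mast markers at 0.560 times. These droplets may hold free RNA of the library, though not with markers of all classes in the same proportion. Damaged erythroid cells within such RNA, an effect of the fusion in this library alone, and its preparation or animals stay open.

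The 24 genes named for the Skida1-deleted library over MLL-ENL in HSPC-like cells had the same direction and a log2 ratio of at least 0.32 in size in erythroid-like cells for 24 of 24 genes, against 8.06% of 4613 eligible genes. After thinning 24 of 24 stayed at least 1.5-fold apart. Thinning draws at random from the same UMIs and hardly alters a ratio of summed CPM. It therefore could not decide on sequencing depth per cell. In erythroid-like cells the deleted library was nearer to Control for 2 of the 24 genes, against 34.9% of the eligible genes. As a set these 24 genes thus did not return toward Control in erythroid-like cells. They were picked for the largest differences between both libraries, which also differ in sex. The count therefore cannot decide on an effect of losing Skida1. Skida1 had 2.25 CPM there in MLL-ENL, against 25.3 CPM in HSPC-like cells, which this count does not cover. A difference shared by all cell classes of both libraries or their animals is a candidate explanation. An effect of the deletion away from Control, and the untested sex, litter and preparation of the animals, stay open.

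The granulocyte-monocyte list was lower in HSPC-like cells of MLL-ENL than of Control, with a median of −1.19. Summed with granulocyte progenitor-like cells the median was −0.69, and in G1 cells it was −0.71, values between the bounds set for cells further toward granulocytes in the Control cluster and for the share of cycling cells. In the summed class the deleted library over Control had −0.79, but both ratios share the 1 Control library, so that anything particular to it would lower both. These explanations and an effect of the fusion therefore cannot be told apart, and animals and preparations, 1 per group, stay open.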

How the results depend on the processing

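Tests chosen only after the results were seen were the 7 alternatives dated so under the processing methods. In all, 24 alternatives gave 3847 values of 307 results. In this part A is MLL-ENL over Control, B is the Skida1-deleted library over MLL-ENL, and C is the deleted library over Control. Genes and lists are log2 ratios in HSPC-like cells, and share ratios and folds are plain ratios. Each reported value but those of antibodies had a counting interval, or for a list a bootstrap interval over its members. Antibody differences moved when they differed by over 1.5-fold in size or went the other way from a value under 0.1. A value turned when it changed direction and that interval lay on 1 side of no difference, and otherwise moved when it left the interval. Where the interval spanned no difference, changes of direction do not count as turned. The cause was not tested for any value that turned or moved.

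Among gene values 1389 stayed within their interval, 825 moved with the same direction or an open one and 54 turned. Among list medians these were 1093, 177 and 44, and among share ratios 88, 71 and 24. Skida1 in B ranged from 0.101-fold to 0.187-fold over 15 alternatives, and in A from 9.89-fold to 30.3-fold over 14. The MLL-fusion target median ranged from 0.29 to 1.12 in A and from 0.29 to 1.14 in C, and the HoxA median from 0.91 to 2.27 in A. The granulocyte-monocyte median ranged from −1.69 to −0.38 in A, the G2M median from −2.94 to −0.36, and the MHC class I median in B from −0.50 to −0.39. B-lineage priming in B ranged from −0.37 to −0.06. The lymphoid priming median in A had the other direction in 2 of 15 alternatives, the HSC program in 5, and the mast program, with 5 members, in 7. Mllt1 in A had it in 6 of 14. None of these counts as turned, since their intervals spanned no difference.

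The loose cell filter moved 86 values, turned 0 and left 185 in place. HSPC-like (0.249), megakaryocyte-like (1.05) and erythroid-like (0.779) share ratios moved in A. Kmt2a (0.83) moved in A. HSPC-like (1.13) share ratio moved in B. Mllt1 (0.085) moved in B. HSPC-like (0.282), megakaryocyte-like (1.77) and erythroid-like (0.983) share ratios moved in C. Kmt2a (0.93) moved in C. The strict cell filter moved 129 values, turned 19 and left 121 in place. HSPC-like (5.38) and basophil-mast-like (1.51) share ratios turned in A. Granulocyte progenitor-like (3.28), megakaryocyte-like (1.57) and erythroid-like (0.764) share ratios moved in A. B-lineage priming (−0.48), interferon response (−0.74), glycolysis (0.034) and immediate early (−0.46) medians turned in A. Cpa3 (1.66), Mcpt8 (0.62), Ebf1 (−1.06), Cd72 (−0.32), Trp53inp1 (−0.16), Srebf2 (−0.0019) and Hspa5 (0.010) turned in A. Kmt2a (0.44) moved in A. HSPC-like (1.9), granulocyte progenitor-like (1.7), erythroid-like (1.0) and B-lineage-like (0.705) share ratios moved in B. MYC and ribosome biogenesis (−0.035) median turned in B. Kmt2a (0.21) moved in B. HSPC-like (10.2) share ratio turned in C. Granulocyte progenitor-like (5.58), erythroid-like (0.766), basophil-mast-like (2.07) and B-lineage-like (0.88) share ratios moved in C. Immediate early (−0.49) median turned in C. B-lineage priming (−0.86) median moved in C. Ctsg (0.57), Bcl11a (−0.38) and Cpa3 (1.89) turned in C. The strict filter left 21 HSPC-like cells in Control and 0 Skida1 UMIs in them, so that no Skida1 ratio to Control was formed.

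Keeping called doublets moved 35 values, turned 2 and left 234 in place. HSPC-like (0.349), megakaryocyte-like (3.42), erythroid-like (0.624) and basophil-mast-like (0.945) share ratios moved in A. Ebf1 (−0.29) turned in A. Erythroid-like (1.32) share ratio moved in B. B-lineage priming (−0.056) median moved in B. Il7r (0.15) turned in B. HSPC-like (0.465), megakaryocyte-like (5.59), erythroid-like (0.826) and basophil-mast-like (1.36) share ratios moved in C. Removing doublets at the expected rate in all libraries moved 27 values, turned 2 and left 242 in place. Basophil-mast-like (1.24) share ratio turned in A. Megakaryocyte-like (2.94) and erythroid-like (0.665) share ratios moved in A. Car1 (−0.28) turned in A. Megakaryocyte-like (4.7), erythroid-like (0.831) and basophil-mast-like (1.63) share ratios moved in C.

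Clustering at resolution 0.5 moved 5 values, turned 4 and left 9 in place. HSPC-like (19.6) and granulocyte progenitor-like (0.196) share ratios turned in A. Megakaryocyte-like (7.91) and erythroid-like (0.556) share ratios moved in A. Megakaryocyte-like (1.44) share ratio moved in B. HSPC-like (26.6) and granulocyte progenitor-like (0.319) share ratios turned in C. Megakaryocyte-like (11.4) and erythroid-like (0.672) share ratios moved in C. Clustering at resolution 2.0 moved 6 values, turned 0 and left 12 in place. HSPC-like (0.205), granulocyte progenitor-like (3.27) and megakaryocyte-like (2.36) share ratios moved in A. HSPC-like (0.289), granulocyte progenitor-like (4.98) and megakaryocyte-like (4.09) share ratios moved in C. Clustering without list genes moved 109 values, turned 7 and left 153 in place. Granulocyte progenitor-like (0.807) share ratio turned in A. HSPC-like (0.61) and megakaryocyte-like (1.51) share ratios moved in A. Megakaryocyte program (−0.076), erythroid program (−0.083), interferon response (−0.14) and immediate early (−0.046) medians turned in A. B-lineage priming (0.024) median moved in A. Kmt2a (0.35) moved in A. HSPC-like (0.844) and granulocyte progenitor-like (1.23) share ratios moved in C. Erythroid program (−0.23) and immediate early (−0.19) medians turned in C. Kmt2a (0.39) moved in C.

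Classes from a marker score per cell moved 150 values, turned 27 and left 94 in place. Basophil-mast-like (1.16) share ratio turned in A. HSPC-like (0.655), megakaryocyte-like (1.55), erythroid-like (0.754) and B-lineage-like (4.01) share ratios moved in A. B-lineage priming (−0.31), megakaryocyte program (−0.10), interferon response (−0.67), MYC and ribosome biogenesis (0.043) and immediate early (−0.27) medians turned in A. Elane (0.44), Hlf (−0.031), Mcpt8 (1.17), Hbb-bt (−0.55), Rsad2 (−0.28), B2m (−0.073) and Cd74 (−1.45) turned in A. Kmt2a (0.18) moved in A. Skida1 was 9.89-fold in A. Granulocyte progenitor-like (0.806), erythroid-like (0.873) and basophil-mast-like (0.795) share ratios turned in B. HSPC-like (1.09), megakaryocyte-like (1.26) and B-lineage-like (0.689) share ratios moved in B. Pbx3 (−0.087) and Egr1 (−0.19) turned in B. Kmt2a (−0.19) and Mllt1 (0.38) moved in B. HSPC-like (0.711), granulocyte progenitor-like (1.11), megakaryocyte-like (1.96), erythroid-like (0.658) and B-lineage-like (2.76) share ratios moved in C. HoxB cluster (−0.43), megakaryocyte program (−0.13), cell cycle inhibitors (−0.33), MYC and ribosome biogenesis (0.17) and immediate early (−0.67) medians turned in C. Hist1h3c (0.28), Kmt2a (−0.016), Bcl11a (−0.0031) and Hlf (−0.17) turned in C. Mllt1 (0.19) moved in C. Skida1 was 1.24-fold in C.

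Classes of the nearest Control cells moved 130 values, turned 20 and left 119 in place. Granulocyte progenitor-like (0.269), megakaryocyte-like (0.824) and erythroid-like (1.16) share ratios turned in A. HSPC-like (0.836) share ratio moved in A. B-lineage priming (−0.16), erythroid program (−0.18), interferon response (−0.37) and immediate early (−0.23) medians turned in A. Elane (0.35), Hoxb4 (−0.20), Hbb-bt (−0.21) and Cd74 (−0.14) turned in A. Kmt2a (0.24) moved in A. Erythroid-like (0.85) share ratio turned in B. HSPC-like (1.44) and granulocyte progenitor-like (1.38) share ratios moved in B. HSPC-like (1.2) and granulocyte progenitor-like (0.37) share ratios turned in C. Megakaryocyte-like (1.37) and erythroid-like (0.989) share ratios moved in C. Erythroid program (−0.15), fetal-neonatal program (−0.065) and immediate early (−0.39) medians turned in C. Hist1h3c (0.14), Bcl11a (−0.083) and Elane (0.68) turned in C. Kmt2a (0.30) moved in C. Skida1 was 1.76-fold in C.

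Shares of named cells moved 7 values, turned 3 and left 8 in place. HSPC-like (0.549), granulocyte progenitor-like (2.07), megakaryocyte-like (2.52), erythroid-like (0.941) and basophil-mast-like (0.96) share ratios moved in A. HSPC-like (0.964), erythroid-like (0.931) and basophil-mast-like (0.899) share ratios turned in B. Granulocyte progenitor-like (1.16) and megakaryocyte-like (1.3) share ratios moved in B. Counting the low-depth cluster as erythroid-like moved 0 values, turned 2 and left 1 in place. Erythroid-like (1.08) share ratio turned in A. Erythroid-like (0.813) share ratio turned in B. Summing HSPC-like and granulocyte progenitor-like cells moved 120 values, turned 9 and left 122 in place. B-lineage priming (−0.14), erythroid program (−0.026), interferon response (−0.27) and immediate early (−0.11) medians turned in A. Hoxb4 (−0.23) and Cd74 (−3.75) turned in A. Kmt2a (0.38) moved in A. Erythroid program (−0.21) and immediate early (−0.24) medians turned in C. Hist1h3c (0.13) turned in C. Kmt2a (0.45) moved in C. Restriction to cells called G1 moved 101 values, turned 24 and left 128 in place. B-lineage priming (−0.19), megakaryocyte program (−0.028), interferon response (−0.34), glycolysis (0.0024) and immediate early (−0.37) medians turned in A. Nusap1 (0.63), Hmmr (0.17), Pimreg (0.30), Birc5 (0.33), Pbk (0.82), Kif11 (0.23), Ebf1 (−0.94) and Cd74 (−0.55) turned in A. Kmt2a (0.31) moved in A. Ebf1 (0.087) turned in B. Immediate early (−0.47) median turned in C. B-lineage priming (−0.55) median moved in C. Pimreg (0.28), Nuf2 (0.084), Aurkb (0.11), Bub1 (0.99), Nusap1 (0.38), Hmmr (0.77), Pbk (0.43), Esco2 (0.55) and Plk1 (0.67) turned in C. Kmt2a (0.40) and Mllt1 (0.13) moved in C.

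Thinning all cells for the sums moved 50 values, turned 2 and left 201 in place. B-lineage priming (−0.025) median turned in A. Kmt2a (0.52) moved in A. Immediate early (−0.047) median turned in C. Kmt2a (0.57) moved in C. Averaging CPM over cells moved 28 values, turned 1 and left 224 in place. Kmt2a (0.57) moved in A. Immediate early (−0.039) median turned in C. Kmt2a (0.62) moved in C. Scaling by median of ratios moved 9 values, turned 0 and left 244 in place. Scaling without the most abundant genes moved 22 values, turned 0 and left 231 in place. Kmt2a (0.79) moved in A. Kmt2a (0.84) moved in C. The larger pseudocount moved 61 values, turned 0 and left 189 in place. Lists with no expression floor moved 1 values, turned 0 and left 87 in place. The other antibody scaling moved 18 values, turned 0 and left 12 in place. The median of all eligible genes in A was −0.07 as reported, 0.02 with the median of ratios and 0.10 without the most abundant genes, and in C it was −0.07, 0.02 and 0.10.

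Per-cell values without thinning moved 4 values, turned 0 and left 2 in place. Summed B-lineage priming per HSPC-like cell moved to 1.44-fold in A. Summed B-lineage priming per HSPC-like cell moved to 1.29-fold in C. HSPC-like cells called S or G2M were 17.4% in MLL-ENL. HSPC-like cells called S or G2M were 15% in the Skida1-deleted library. Dropping Bcl11a and Tcf3 moved 1 values, turned 2 and left 0 in place. Summed B-lineage priming per HSPC-like cell turned to 0.953-fold in A. Summed B-lineage priming per HSPC-like cell moved to 0.859-fold in B. Summed B-lineage priming per HSPC-like cell turned to 0.819-fold in C. Skida1 over all barcodes moved 0 values, turned 0 and left 3 in place. Skida1 over all kept cells moved 0 values, turned 0 and left 3 in place.

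No paired analysis was possible because each group had 1 library and all libraries were replicate 1. No value above comes from a test. Lists and genes of classes other than HSPC-like were not recomputed under the alternatives, and those of the HoxB list in B and C gave no value in 3 alternatives for want of measured members. Depth limits rare genes, and Skida1 itself rested on 18 UMIs in Control. The HSPC-like class held different clusters in Control than in the fusion libraries. Classes from a marker score turned 27 values and G1 cells 24, the most of the alternatives run. The G1 call itself used the S and G2M lists, so that it selects cells with few transcripts of division genes.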

Other observations

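No value in this part comes from a test, and the counts of shared genes in other classes were chosen after the values of HSPC-like cells were seen. In HSPC-like cells of MLL-ENL, lists of HoxB genes, of platelet and red cell programs and of cell cycle inhibitors stood above Control, but with classes from a marker score the megakaryocyte median was −0.10. Of 2 measured HoxB genes 2 were higher, Hoxb2 (log2 ratio 2.36) and Hoxb4 (0.79), with a median of 1.57. Hoxb4 had −0.20 with classes of the nearest Control cells and −0.23 in the summed class. In the deleted library 3 HoxB genes had a median of −0.12 against MLL-ENL and of 1.0 against Control (−0.43 with classes from a marker score). The megakaryocyte program had 2 of 9 genes higher and 0 lower (median 0.26), led by Gp9, a platelet glycoprotein (1.30), and its medians in the deleted library were 0.07 against MLL-ENL and 0.32 against Control (the latter −0.13 with the marker score). The erythroid program had 5 of 12 genes higher and 1 lower (median 0.51, but −0.18 with classes of the nearest Control cells), including the globin gene Hbb-bt (0.83, but −0.55 with the marker score) and the carbonic anhydrase Car1 (0.78, but −0.28 with doublets removed at the expected rate in all libraries), with medians of −0.18 and 0.42 in the deleted library. The latter was −0.23 when clustered without list genes, −0.15 with classes of the nearest Control cells and −0.21 in the summed class of HSPC-like and granulocyte progenitor-like cells. The cell cycle inhibitors had 3 of 8 genes higher (median 0.44), led by Cdkn1c, of quiescent stem cells (1.34), and Btg1, an antiproliferative gene (1.26), with −0.04 and 0.50 in the deleted library (the latter −0.33 with the marker score). The adult-like program had 4 of 14 genes higher and 1 lower (median 0.19), with Cd48, a leukocyte antigen, at −2.10, and medians of −0.11 and 0.44 in the deleted library. Against Control this list had the other direction in 6 of 15 alternatives in MLL-ENL and in 7 in the deleted library. Cyp11a1, a steroid synthesis gene of mast cells, had 1.02 and Gata2, a stem and mast cell factor, 0.77. The mast list had medians of 0.21 in the deleted library against MLL-ENL and −0.49 against Control (of the other direction in 7 of 15 alternatives).

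Chromatin and signalling genes went both ways in MLL-ENL over Control. The Polycomb list had 4 of 27 genes higher and 3 lower (median 0.19), with the methyltransferase Ezh2 at −1.77 and its cofactor Jarid2 at 1.18, and its medians in the deleted library were −0.00 against MLL-ENL and 0.11 against Control. The MLL and elongation complex had 6 of 18 genes higher and 1 lower (median 0.05), led by the elongation factors Ell2 (1.98) and Aff4 (1.28), with −0.03 and 0.12 in the deleted library. Of 28 genes of cytokine receptors and signalling 8 were higher and 2 lower (median 0.21), including Cish, a cytokine feedback gene (1.44), and Csf1r, the macrophage growth factor receptor (−1.19). In the deleted library over MLL-ENL that list had a median of −0.13 at percentile 0.62, with the feedback gene Socs1 at −0.58, and over Control 0.11. Homing and adhesion genes had 4 of 14 higher and 1 lower (median 0.04), with the integrins Itgam (1.40) and Itgal (0.69). Their medians in the deleted library were −0.11, with the chemokine receptor Cxcr4 at −0.59, and 0.08.

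Medians of 4 metabolic and chaperone lists lay below 0 in both fusion libraries over Control. In MLL-ENL oxidative phosphorylation had 5 of 23 genes lower and 3 higher (median −0.35), among them Ndufv1 of complex I (0.50-fold) and Atp5e of the ATP synthase (1.04). Its medians in the deleted library were −0.08 against MLL-ENL and −0.51 against Control. Glycolysis had 3 of 15 genes lower (median −0.30), including Pgam1 (−1.64) and Gapdh (−0.88), but its median was 0.034 under the strict filter and 0.0024 in G1 cells. It had −0.03 in the deleted library over MLL-ENL, where Hk2 had 0.68, and −0.30 over Control (0.23 with the marker score). Cholesterol synthesis held Fdps (−1.41) and its regulator Srebf2 (1.03, but −0.0019 under the strict filter), and its medians in the deleted library were 0.05, with Dhcr7 at 0.73, and −0.32. Heat shock genes held the mitochondrial chaperone Hspd1 (−1.26) and the chaperone Hspa5 of the endoplasmic reticulum (0.50-fold, but a log2 ratio of 0.010 under the strict filter), with medians in the deleted library of 0.08 and −0.65.

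The interferon list of MLL-ENL held Isg15 at −1.90 and Rsad2 at 0.98 (but −0.28 with the marker score), and its medians in the deleted library were −0.07 against MLL-ENL, with Ifit3 at −0.68, and 0.23 against Control (of the other direction in 7 of 15 alternatives). Of the MHC class I list Psmb8, of the immunoproteasome, had −0.73 and B2m 0.66 (but −0.073 with classes from a marker score). The MHC class II list had 4 genes measured (median −0.04), with the invariant chain Cd74 at 1.05 (but −1.45 with classes from a marker score), and medians of −0.33 and −0.32 in the deleted library. With HSPC-like and granulocyte progenitor-like cells summed, 5 of 6 genes were lower in MLL-ENL than in Control (median −2.53), with Cd74 at −3.75, and 5 of 6 in the deleted library (median −3.25). That sum took in the granulocyte progenitor-like class, whose composition differed between Control and the fusion libraries. The p53 targets had 2 of 11 genes lower and 1 higher (median −0.21), with Trp53inp1 at 1.22 (but −0.16 under the strict filter) and Gtse1, a mitotic gene, at −2.18. Their medians in the deleted library were −0.07 and −0.06. In the deleted library over Control the immediate early list had a median of 0.16, but the other direction in 8 of 15 alternatives (−0.67 with the marker score), and the HSC program 0.46, with the other direction in 5. The sex-linked list had a median of 1.44 in MLL-ENL and 5.07 in the deleted library against each of the others, with 4 genes higher and 2 lower.

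Of the 24 genes named for MLL-ENL over Control, 22 had the same direction with a log2 ratio of at least 0.32 in size in granulocyte progenitor-like cells, 22 in megakaryocyte-like, 16 in erythroid-like and 22 in basophil-mast-like cells. Among 5026 eligible genes these shares were 52.6%, 37.5%, 33.2% and 39.6%. At the higher clustering resolution a lymphoid progenitor-like class appeared, with 0.278% of kept cells in Control, 4.09% in MLL-ENL and 4.47% in the deleted library. Per thinned cell of this class, the B-lineage list in MLL-ENL summed to 0.599 times the Control level [0.465–0.783] and in the deleted library to 0.607 times [0.471–0.793], from 15 Control cells, and the deleted library was 1.01-fold MLL-ENL [0.930–1.10]. The lymphoid list had 1.07 [0.915–1.27] and 1.19 [1.01–1.40]. Median CD127 counts of this class were 28, 6 and 4 in Control, MLL-ENL and the deleted library, so its cells were not alike. Single genes were not compared in this class.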
